A study of Mus musculus with 84 samples.

How the data were processed

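Per the labels, salivary glands of ICR embryos were frozen in embedding medium and sectioned, the sections were stained, and the places were cut out by laser microdissection. RNA was taken up with Trizol or with RNeasy Micro kits and amplified in 2 rounds, and the product was labelled with Cy3 for 1-colour arrays. Which samples were extracted with which kit is not given in the sources used here. The authors deposited 6 tables of arrays, 1 for each of 4 ages, 1 for the buds over age and 1 for the main ducts over age, together with sheets of fold changes, notes on their test and a table of pathways.

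The log2 values were deposited by the authors as normalised processed signals of the scanner software, 1 column per array, per the file headers. Their scaling and centring are not given in the sources used here. The authors' p-value of each probe comes from a one-way analysis of variance over the groups of its table, uncorrected, with Tukey's post hoc test, and the deposited tables keep only probes with a p-value of at most 0.05 after a filter on detection flags. The authors' fold changes were deposited as signed ratios, negative where the first group is lower. Of 13096 entries in 33 fold sheets, 10257 lay within 0.01 log2 of the difference of the deposited group means and 64 had the opposite sign. By sheet the share within 0.01 ran from 37.1% to 92.9%, and 2002 of the 2839 differing folds were smaller than the difference of means. In the array tables themselves, 95.7% of the fold entries lay within 0.01 log2. How the differing folds were made is not given in the sources used here, so the differences of array means were used.

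The tables held 3844 entries at E12.5, 3698 at E13.5, 2282 at E14, 5312 at E15, 7604 for buds and 7717 for main ducts. Control probes were dropped, 2, 13, 1, 7, 13 and 13 of them in that order, which left 3842, 3685, 2281, 5305, 7591 and 7704 probes. Symbols were brought up to date through the RefSeq accession of each probe, with names only from the mouse assembly GRCm38.p6, and 335, 339, 202, 482, 729 and 686 symbols changed. A gene was represented by its probe with the highest mean over the groups compared, which gave 3149, 3091, 1983, 4369, 6053 and 6011 genes. No value was missing or imputed. Columns were matched to groups by the age and place in their names, and all 56 columns had a group. The columns carry no replicate numbers of the labels, so array numbers in the text are counted in column order within a group, and slides are numbered 1 to 17 by the slide in the column names.

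Each comparison was fitted with limma (version 3.58.1, R 4.3.3) by lmFit and eBayes on the deposited log2 values, with the groups of a table sharing 1 estimate of spread. The adjusted p is Benjamini-Hochberg over all probes of the table. Genes passed at an adjusted p below 0.05, with no rule of size. The change of the bud to main duct difference from E12.5 to E15 was an interaction term over 1287 probes found in both tables, for 19 arrays. All 20 comparisons, their designs, the gene lists and most alternatives were chosen before the data were examined. The rest of the alternatives were added after, and are named as such in the sensitivity part.

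For each comparison the text names genes from the 8 largest differences in each direction among those that passed, 1 probe per gene, without clone names. From each list it takes up to 4 members with the largest difference and any member against the majority. The exceptions, chosen after their values were seen, were Aqp5, Lpo and Bhlha15 at E15. A few results that this rule would name are not reported here. The 17 lists hold 345 members: FGF response and end bud progenitor, WNT pathway, hedgehog, EDA and Notch pathways, acinar and secretory, ductal, stratified epithelial, epithelial identity, basement membrane, cleft and matrix remodelling, cell cycle, immediate early and heat shock, housekeeping, and markers of mesenchyme, endothelial, neural and glial, blood and immune, and muscle cells. A member absent from a table was counted as not measured. Lists with at least 3 measured members were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg over the lists of a comparison. Of 249 list tests 57 passed, and 4 passed with an estimated correlation.

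Slide was fitted as a fixed block at E12.5 and E15, where groups share slides, and as a random block (statmod 1.5.0) at E13.5 and over age. The consensus correlation within slides was 0.148 at E13.5 and for main duct over age, -0.29 for bud over age and 0.239 for the interaction. At E13.5 only the secondary duct arrays lay on more than 1 slide, so the value there rests on them. The random block thus cannot remove a slide difference between the other places. At E14 each place has its own slide. Two-sided exact permutation tests were used for the location score, over 4 comparisons with Benjamini-Hochberg adjustment. Splits of the arrays were counted with the real one included, at most 100 per comparison, drawn with seed 1 where more exist. Scripts ran under Python 3.11.15 with numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.

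The fits were tested on simulated changes. In each of 7 comparisons, 100 probes were shifted by log2 1 and another 100 by log2 2 in simulated arrays with the real group sizes, no other difference and each probe's own spread. For E12.5 bud against main duct (3842 probes), 44% and 72% of the shifted probes were recovered, with 6 unshifted probes among 122 called. For E13.5 central bud (3685 probes) these were 6% and 47%, with 5 of 58, for E14 (2281 probes) 23% and 62%, with 9 of 94, and for E15 (5305 probes) 23% and 64%, with 4 of 91. For bud over age (7591 probes) they were 21% and 64%, with 1 of 86, for main duct over age (7704 probes) 14% and 52%, with 1 of 67, and for the interaction (1287 probes) 9% and 60%, with 2 of 71.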

Results

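Gene expression was measured in laser microdissected epithelium of the embryonic submandibular salivary gland of ICR mice, to compare end buds, clefts and ducts with one another and from one age to the next. The places were picked by their position in stained sections, and the pieces of many buds, clefts or ducts were pooled for each array. The labels list 84 samples in 14 groups, and 56 arrays on 17 slides carry values in the 6 deposited tables. At E12.5 there were 3 bud, 4 cleft and 4 main duct arrays. At E13.5 there were 3 peripheral bud, 4 central bud, 4 cleft, 3 main duct and 3 secondary duct arrays. At E14 there were 3 bud, 4 main duct and 4 secondary duct arrays, and at E15 there were 5 bud, 7 main duct and 5 secondary duct arrays. The number of arrays limits the precision of every value below.

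Differences are in log2 units, the first-named group minus the second, with the standard error after ±. A gene passed when its adjusted p was below 0.05 in limma over the probes of the table, and the words higher, lower, rose and fell are kept for genes that passed. Each table lists only probes that had already passed an uncorrected test by the authors on the same arrays. Counts adjusted over all 14329 distinct probes of the 6 tables are therefore given as well. These probes, too, had each passed that test in some table, so this adjustment is only a partial remedy for the selection. The labels do not tie captured regions to animals, so arrays of one group may share animals. The p-values measure only the spread between arrays and may be too small. The gene lists were fixed before the files were seen, and unless another number follows, the count adjusted over the list alone was the same as the count over all genes. A list's shift was tested with camera at a preset correlation, followed by its p-value with an estimated correlation.

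At E12.5, the bud was separated from the main duct by higher FGF-responsive and end bud progenitor genes and by lower keratin and barrier genes, with 3 bud arrays against 4 main duct arrays. In the list of FGF response and end bud progenitor genes, 11 of 13 were higher in bud and 2 were lower, with a median of 0.71. Etv4, an ETS factor induced by FGF signalling, differed by 2.86 ± 0.61 (adjusted p = 0.00669), and Sox10, a transcription factor of salivary progenitors, by 2.60 ± 0.33 (adjusted p = 0.000556). Shisa2, which restrains FGF and WNT receptors, was higher by 2.38 ± 0.26 (adjusted p = 0.000311). Against the majority, the guidance cue Sema3c was lower, at -3.03 ± 0.76 (adjusted p = 0.0123). In the ductal list, 12 of 17 genes were lower in bud, 1 was higher and 4 did not pass, with a median of -1.16 (13 lower, 1 higher and 3 not past when adjusted over the list alone). The chloride channel Cftr was lower, at -4.15 ± 0.60 (adjusted p = 0.00105), Krt19 at -3.50 ± 0.48 (adjusted p = 0.000748) and Krt15 at -3.44 ± 0.20 (adjusted p = 8.06e-06). Krt23 was higher by 3.47 ± 0.36 (adjusted p = 0.000209). The FGF list had a camera adjusted p = 0.0205, and adjusted p = 0.112 with an estimated correlation. For the ductal list these were 1.33e-05, and adjusted p = 0.112 with an estimated correlation.

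The largest E12.5 list shift was in stratified epithelial differentiation, where 12 of 13 genes were lower in bud than in main duct and none was higher, with a median of -2.83. Sprr1a, a cornified envelope precursor, was lower, at -5.16 ± 0.31 (adjusted p = 8.06e-06), the desmosomal cadherin Dsc2 at -4.53 ± 0.61 (adjusted p = 0.000728) and the suprabasal keratin Krt1 at -3.67 ± 0.49 (adjusted p = 0.000678). This shift held under both correlations (adjusted p = 6.2e-08, and 0.00574 with an estimated correlation). Genes outside the lists included the stefins Stfa1, a cysteine protease inhibitor, at -7.37 ± 1.16 (adjusted p = 0.00165) and Stfa3 at -7.34 ± 0.66 (adjusted p = 0.00011). Sulf1, an extracellular heparan endosulfatase, was lower in bud, at -5.45 ± 0.58 (adjusted p = 0.000228), whereas Hs3st3a1, a heparan sulfate sulfotransferase, was higher by 6.02 ± 0.30 (adjusted p = 4.43e-06). The semaphorin Sema3b was higher by 5.94 ± 0.47 (adjusted p = 6.63e-05), the chemokine Ccl20 by 5.64 ± 0.89 (adjusted p = 0.00168) and Aldh1a3, which makes retinoic acid, by 4.35 ± 0.87 (adjusted p = 0.00503).

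Immediate early and epithelial identity genes were also lower in E12.5 bud as lists. Of 7 immediate early and heat shock genes, 6 were lower in bud and 1 was higher, with a median of -2.03 (adjusted p = 0.0149, and adjusted p = 0.229 with an estimated correlation). Jun was among the lower genes, at -2.98 ± 0.49 (adjusted p = 0.00197). Of 11 epithelial identity genes, 4 were lower and 7 did not pass, with a median of -0.84 (adjusted p = 0.0113, and adjusted p = 0.229 with an estimated correlation). The adherens junction cadherin Cdh1 was lower, at -1.44 ± 0.26 (adjusted p = 0.00304). The remaining lists were not shifted as a whole. Tnfrsf19, a TNF receptor family member, was higher by 3.02 ± 0.58 (adjusted p = 0.0042) and Edar, the ectodysplasin receptor, by 2.22 ± 0.38 (adjusted p = 0.00219). Their list of hedgehog, ectodysplasin and Notch genes had 4 higher and 1 lower of 7. Ccnd1, a G1 cyclin, was higher by 2.74 ± 0.31 (adjusted p = 0.000331) among 8 cell cycle genes of which 5 were higher. The laminin chain Lama3 was lower, at -3.77 ± 0.67 (adjusted p = 0.0029). Its basement membrane list had 4 higher and 2 lower of 8 (5 and 2 adjusted over the list alone). In the WNT list 2 genes were higher and 6 lower of 10 (3 and 6 adjusted over the list alone), among them the WNT inhibitor Sfrp1 at 1.44 ± 0.27. Of 4 acinar genes 3 were higher and 1 lower, of 4 cleft and matrix genes 2 and 1, of 5 housekeeping genes 4 and 1, and of 3 mesenchyme genes 0 passed. The endothelial list had 1 measured member at this age, and the neural, blood and muscle lists had 0.

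In total, 1006 genes were higher and 642 lower in E12.5 bud than in main duct, 1648 of 3149 genes, and 658 passed when adjusted over all 14329 probes. In the tables over age, whose probes the authors chose on differences between ages, 15 were higher and 27 lower, 42 in all. These tables also hold arrays of other ages. Leaving out bud array 1, 2 or 3 gave 1007, 864 and 1032 genes. Buds and main ducts shared slides 12 to 14 at this age, and with slide as a block 1645 genes passed. The median over all probes was 0.30, and the share of passing genes that were higher moved from 61.0% to 50.8% after quantile normalization and to 44.0% after centring each group.

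The E12.5 cleft was close to the bud and far from the main duct. Against the bud, 5 genes were higher and 9 lower of 3149, with 4 cleft and 3 bud arrays, and 760 had an unadjusted p under 0.05. Krt5, a basal keratin, was lower, at -2.85 ± 0.41, Krt75, another keratin, at -2.92 ± 0.40 and Aldh1a1, a retinal dehydrogenase, at -2.46 ± 0.40, each with adjusted p = 0.0341. Slc2a3, a glucose transporter, was higher by 2.27 ± 0.36 (adjusted p = 0.0341) and the immunophilin Fkbp5 by 3.64 ± 0.60 (adjusted p = 0.0364). None of the 14 genes passed over all 14329 probes. Leaving out cleft array 1 or any 1 of the 3 bud arrays left 0 genes in limma. Leaving out cleft array 2 or 4 gave 26 and 31. The ductal list had a median of -0.94, and 1 of its 17 genes passed (10 lower adjusted over the list alone). It had adjusted p = 1.26e-05, and adjusted p = 0.294 with an estimated correlation and 0.135 after quantile normalization. After quantile normalization the count became 48 and the share that was higher moved from 35.7% to 50.0%.

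Against the main duct, the E12.5 cleft had 1434 genes higher and 1056 lower, 2490 in all, with 4 arrays in each group. All 13 stratified epithelial genes were lower in cleft, with a median of -3.41 (adjusted p = 3.68e-07, and 0.00761 with an estimated correlation). The desmosomal plakophilin Pkp1 was lower, at -6.23 ± 0.60 (adjusted p = 6.6e-05). Of 17 ductal genes 16 were lower and 1 was higher, with a median of -2.43 (adjusted p = 4.18e-07, and adjusted p = 0.094 with an estimated correlation). Krt5 differed by -5.92 ± 0.38 (adjusted p = 8.4e-06). All 11 epithelial identity genes were lower, with a median of -1.30 (adjusted p = 0.00049, and adjusted p = 0.19 with an estimated correlation). Ocln, which encodes occludin, was lower, at -3.72 ± 0.85 (adjusted p = 0.00509). The glycerol channel Aqp3 was lower, at -8.13 ± 0.91 (adjusted p = 0.000129). The laminin chain Lama4 was higher by 4.65 ± 0.92 (adjusted p = 0.00267), and Pdgfra, a mesenchymal growth factor receptor, was higher by 2.38 ± 0.76 (adjusted p = 0.0174). Over all probes the median was 0.44, and 1508 genes passed when adjusted over 14329 probes, without Pdgfra. After centring 1034 genes were higher and 1128 lower.

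At E13.5, both bud groups again had lower ductal keratins and stratified genes than the main duct, and higher cell cycle genes. Central bud (4 arrays) differed from main duct (3 arrays) by 971 genes higher and 1075 lower, and peripheral bud (3 arrays) by 1061 higher and 1241 lower, of 3091. In the cell cycle list, 14 of 18 genes were higher in central bud and none was lower, with a median of 1.15. In peripheral bud 13 were higher and 1 lower (14 and 1 adjusted over the list alone), with a median of 1.13. Ccnd1 was higher in central bud by 3.10 ± 0.51 (adjusted p = 0.00096) and the S phase cyclin Ccne1 by 2.88 ± 0.50 (adjusted p = 0.00131). Of 9 FGF response genes, 8 were higher in central bud and none lower, and 7 were higher and 1 lower in peripheral bud, with medians of 1.88 and 1.72. Sox10 was higher in central bud by 2.50 ± 0.52 (adjusted p = 0.00312) and Dusp6, a feedback phosphatase of FGF signalling, by 1.94 ± 0.35 (adjusted p = 0.00162). Of 16 ductal genes, 12 were lower and 1 was higher in central bud (13 and 1 in peripheral bud), with medians of -2.37 and -2.63. Krt19 was lower in central bud, at -5.56 ± 1.05 (adjusted p = 0.00203), and Krt23 was again higher, by 2.76 ± 0.55 (adjusted p = 0.00256).

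Among 12 stratified epithelial genes at E13.5, 9 were lower and 1 was higher in each bud group than in the main duct, with medians of -3.47 in central and -3.70 in peripheral bud. Sprr1a was lower in central bud, at -7.41 ± 1.11 (adjusted p = 0.000668) and Ly6d at -6.87 ± 1.54 (adjusted p = 0.00408). Krt16 was higher by 4.82 ± 0.66 (adjusted p = 0.000454). Of 11 epithelial identity genes, 8 were lower in central bud and all 11 in peripheral bud, with medians of -1.60 and -2.33. The splicing factor Esrp1 was lower in central bud, at -2.55 ± 0.59 (adjusted p = 0.00458). Of 5 WNT genes, 1 was higher and 4 lower in central bud, among them the ligands Wnt5b at -5.75 ± 1.21 (adjusted p = 0.00316) and Wnt10a at -3.41 ± 0.53 (adjusted p = 0.00085). The Notch target Hes1 was lower, at -5.98 ± 1.41 (adjusted p = 0.00497). For central bud the 5 shifted lists, which were cell cycle, FGF, ductal, stratified and epithelial identity, had adjusted p from 0.00469 to 0.0116, and adjusted p = 0.234 with an estimated correlation for all but epithelial identity, at 0.238. For peripheral bud they had adjusted p from 0.00316 to 0.0273, and adjusted p = 0.258 with an estimated correlation for each.

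The largest E13.5 differences between bud and main duct exceeded those at any other age. Tcaf1, a regulator of a cation channel, was higher in central bud by 10.66 ± 1.64 (adjusted p = 0.000773) and Ido2, a tryptophan-degrading enzyme, by 9.17 ± 1.10 (adjusted p = 0.000281). The peptide hormone Insl5 was lower, at -12.96 ± 2.48 (adjusted p = 0.0021). A set of 114 probes lay at least 32-fold from the main duct in both bud groups. On an axis from bud (0) to main duct (1) over the probes of this set that were measured in a group, the 3 secondary duct arrays ran from 0.104 to 1.01, with the highest value in the only one from slide 2. The E12.5 main duct arrays lay at 0.204 to 0.285 and the E14 bud arrays at 0.476 to 0.643. All E13.5 main duct arrays were on slide 1 and no bud array was, so slide and place cannot be told apart in these comparisons. Adjusted over all 14329 probes, 1155 and 1466 genes passed for central and peripheral bud, and the medians over all probes were -0.47 and -0.60. Leaving out main duct array 2 lowered the central bud count to 1323. Quantile normalization moved the higher share of passing genes from 47.5% to 58.1% in central bud, with 57.7% after centring, and from 46.1% to 58.8% in peripheral bud.

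**Figure D1:**
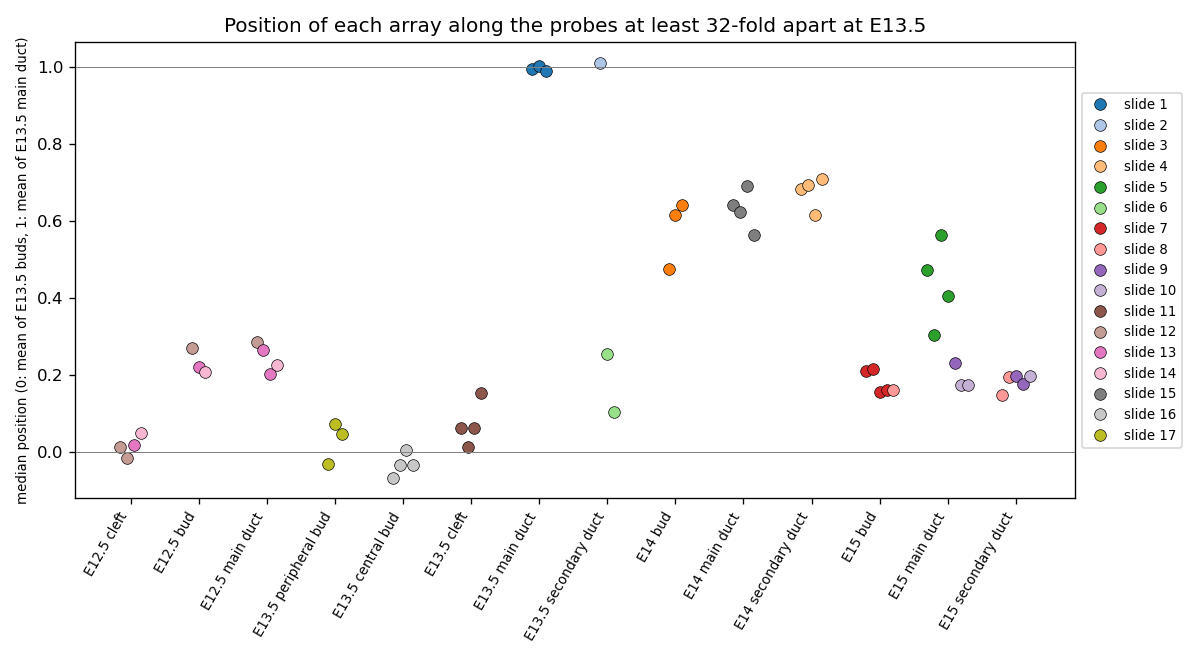
Position of each array along the axis from bud (0) to main duct (1) at E13.5, as the median over those of the 114 probes at least 32-fold apart there that were measured in the group, from 20 in E12.5 cleft to all 114 at E13.5, so groups rest on different probes. The E13.5 main duct arrays lie at 0.991 to 1.00 and the E12.5 main duct arrays at 0.204 to 0.285, and 1 of the 3 E13.5 secondary duct arrays lies at 1.01.

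Few genes passed between the E13.5 bud groups and the cleft. Peripheral and central bud differed by 0 genes in limma, with 155 at an unadjusted p under 0.05, and peripheral bud and cleft by 0 genes, with 321. As a list, epithelial identity genes were shifted between peripheral and central bud, with a median of -1.01 (adjusted p = 0.000445, and adjusted p = 0.313 with an estimated correlation). So were cleft and matrix genes at -1.06 (adjusted p = 0.0254, and adjusted p = 0.313 with an estimated correlation). No member passed in either list. Central bud and cleft (4 arrays each) differed by 2 genes higher and 4 lower, with 624 at an unadjusted p under 0.05. The kinase Src was higher in central bud by 1.84 ± 0.33 (adjusted p = 0.0371) and the splicing factor Sf3b1 by 2.69 ± 0.45 (adjusted p = 0.0342). Nfkbie, an inhibitor of NF-kappa-B, was lower, at -4.47 ± 0.66 (adjusted p = 0.0265). None of the 6 passed over all 14329 probes, 0 passed in limma with slide as a random block, and 42 genes passed in another split of the same arrays. Leaving out any 1 of the 8 arrays gave between 0 and 143, the highest without cleft array 3. After quantile normalization 16 genes passed, with 56.2% higher in place of 33.3%. Blood and immune genes were shifted as a list between central bud and cleft, with a median of -2.68 (adjusted p = 0.00617, and adjusted p = 0.338 with an estimated correlation). None passed over all genes, and adjusted over the list alone 2 did, the haem synthesis gene Alas2 and the alpha globin Hba-a1. Ductal genes (median 0.72, adjusted p = 0.0197, and 0.397 with an estimated correlation) and cell cycle genes (0.64, adjusted p = 0.0221, and 0.414) were shifted the other way. In peripheral bud against cleft, cell cycle (0.45) and blood genes (-2.43) were shifted with adjusted p = 0.023 each, and neither passed with an estimated correlation. The median over all probes was 0.17 for central bud against cleft. Leaving out cleft array 3 or 4 gave 1 gene for peripheral bud against cleft.

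Counts against the E13.5 secondary duct depended on single arrays, and its 3 arrays correlated with one another at only 0.247, -0.07 and -0.144. Peripheral bud and secondary duct (3 arrays each) differed by 260 genes higher and 373 lower. Among the lower were the microfibril protein Mfap2 at -5.12 ± 1.21 (adjusted p = 0.0328) and Krt19 at -4.16 ± 1.13 (adjusted p = 0.0377). In the ductal list 5 of 16 genes were lower (7 adjusted over the list alone), and no list was shifted as a whole. None of the 633 passed over all 14329 probes, and 0 passed in limma with slide as a random block. The count ran from 0 without peripheral bud array 2 or secondary duct array 1 to 1335 without secondary duct array 3. It was 87 without peripheral bud array 1, 1 without peripheral bud array 3 and 153 without secondary duct array 2. Quantile normalization and centring moved the higher share from 41.1% to 58.7% and 58.0%. Central bud (4 arrays) and secondary duct differed by 14 genes higher and 1 lower, among them Sesn2, a stress-induced sestrin, at 3.90 ± 0.59 (adjusted p = 0.0118) and Mdm4, a p53 regulator, at -1.86 ± 0.38 (adjusted p = 0.0464). Of these 15, 2 passed over all 14329 probes and 0 in limma with slide as a random block. The count ran from 0 to 1025 when any 1 of the 7 arrays was left out, the highest without secondary duct array 3. Main and secondary duct (3 arrays each) differed by 1 gene higher, Sectm1b at 4.07 ± 0.61 (adjusted p = 0.0154), and 6 lower. Among the lower genes were Id4, an inhibitor of basic helix-loop-helix factors, at -3.41 ± 0.64 (adjusted p = 0.0456) and the lactate transporter Slc16a3 at -4.34 ± 0.74 (adjusted p = 0.024).

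As lists, epithelial identity (median 1.44), ductal (1.36), stratified (1.58), FGF (-0.91) and cell cycle genes (-0.50) were shifted between E13.5 main and secondary duct, with camera adjusted p from 0.000638 to 0.0188. With an estimated correlation these became adjusted p = 0.21 for the epithelial identity and FGF lists and adjusted p = 0.222 for the others. No member passed over all genes, and adjusted over the list alone 3, 1 and 1 genes were higher and 0 and 1 were lower, in that order. None of the 7 genes between the ducts passed over all 14329 probes, 0 passed in limma with slide as a random block, and leaving out any 1 of the 6 arrays gave between 0 and 411 genes, the highest without secondary duct array 1. After quantile normalization 1 gene was left, with 0% higher in place of 14.3%. Central bud array 3 and secondary duct array 3 correlated at r = 0.901 across probes, although they carry different labels. Without both of them 1002 genes passed between central bud and secondary duct, 1304 between peripheral bud and secondary duct, and 1 between main and secondary duct. The medians over all probes were -0.15 and -0.16 for central and peripheral bud against secondary duct and 0.21 for main against secondary duct.

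At E14 ductal genes such as Krt7 were lower in bud than in main duct, with 3 bud and 4 main duct arrays. Krt7 was lower, at -5.21 ± 0.31 (adjusted p = 2.33e-05), Krt19 at -4.05 ± 0.40 (adjusted p = 0.000435), Cftr at -4.09 ± 0.67 (adjusted p = 0.00453) and the ductal transcription factor Tfcp2l1 at -3.70 ± 0.28 (adjusted p = 0.000113). In the ductal list 10 of 14 genes were lower and 1 was higher, with a median of -1.64 (adjusted p = 0.000561, and adjusted p = 0.155 with an estimated correlation). All 7 immediate early and heat shock genes were lower, with a median of -3.12 (adjusted p = 0.00307, and adjusted p = 0.221 with an estimated correlation). Examples were Fos at -5.56 ± 0.81 (adjusted p = 0.00284) and Jun at -3.13 ± 0.26 (adjusted p = 0.000161). Wnt10a was lower, at -5.47 ± 0.72 (adjusted p = 0.00183) and Wnt6 at -2.90 ± 0.51 (adjusted p = 0.00615). Their WNT list had 1 higher and 3 lower of 6 (1 and 4 adjusted over the list alone). Of 11 cell cycle genes 8 were higher and 1 was lower, with a median of 0.87 (adjusted p = 0.00752, and adjusted p = 0.221 with an estimated correlation). Cdkn1a, a cyclin-dependent kinase inhibitor, was lower, at -4.57 ± 1.10 (adjusted p = 0.0155). Of 4 acinar genes 3 were higher and 1 was lower, among them the water channel Aqp5 at 3.34 ± 0.88 (adjusted p = 0.02). Sox10 was higher by 3.35 ± 0.69 (adjusted p = 0.0106), in an FGF list with 2 higher and 1 lower of 8.

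Of 4 stratified genes at E14, 3 were lower in bud than in main duct, with a median of -2.47 (adjusted p = 0.0216, and adjusted p = 0.155 with an estimated correlation). Of 8 epithelial identity genes 5 were lower, with a median of -1.08 (adjusted p = 0.0232, and adjusted p = 0.24 with an estimated correlation). The cytochrome Cyp2f2 was lower, at -8.08 ± 0.67 (adjusted p = 0.000161), as was the pro-apoptotic Bmf, at -8.24 ± 1.16 (adjusted p = 0.00244). The mucosal chemokine Cxcl17 was lower, at -6.32 ± 0.43 (adjusted p = 5.05e-05) and Timp3, a metalloproteinase inhibitor, at -3.56 ± 0.33 (adjusted p = 0.000351). The casein Csn1s1 was higher by 6.70 ± 1.56 (adjusted p = 0.0146), or 4.31 in the authors' deposited fold. In total 400 genes were higher and 536 lower of 1983, against 137 and 164 among the probes of the tables over age. Over all 14329 probes 94 passed, and Aqp5, Sox10, Cdkn1a and Csn1s1 did not. Leaving out bud array 1, 2 or 3 gave 429, 544 and 610 genes, and quantile normalization moved the higher share from 42.7% to 53.2%. The 3 places were on separate slides at E14, so slide and place cannot be told apart, and the median over all probes was -0.10. Among the E14 columns only those of main duct carry a wash mark in their names. What the mark stands for is not given in the sources used here, and it cannot be told apart from place either.

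Against the E14 secondary duct (4 arrays), 179 genes were higher and 244 lower in bud, 423 in all. Of 14 ductal genes 8 were lower and none was higher (12 lower adjusted over the list alone), with a median of -1.29 (adjusted p = 9.73e-06, and adjusted p = 0.0657 with an estimated correlation). Krt7 differed by -3.82 ± 0.31 (adjusted p = 0.000405) and Tfcp2l1 by -2.90 ± 0.28 (adjusted p = 0.000886). Cyp2f2 was lower, at -6.35 ± 0.67 (adjusted p = 0.000907) and Cxcl17 at -4.24 ± 0.43 (adjusted p = 0.000886). Of 8 epithelial identity genes 5 were lower (6 adjusted over the list alone), with a median of -1.11 (adjusted p = 0.00452, and adjusted p = 0.249 with an estimated correlation). Of 7 immediate early genes 2 were lower, with a median of -1.52 (adjusted p = 0.0112, and adjusted p = 0.309 with an estimated correlation). The count was 23 over all 14329 probes and ran from 72 to 230 when any 1 of the 7 arrays was left out. Secondary duct arrays 2 and 3 correlated at r = 0.942, and averaging them gave 98 genes.

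E14 main and secondary duct (4 arrays each) differed by 382 genes higher and 213 lower, 595 in all. Krt17, a keratin, was higher in main duct by 2.80 ± 0.49 (adjusted p = 0.0187) and Krt19 by 1.92 ± 0.37 (adjusted p = 0.0226). In their list 5 of 14 ductal genes were higher and 1 lower. Wnt6 was higher by 2.81 ± 0.47 (adjusted p = 0.0168) and Wnt10a by 3.46 ± 0.66 (adjusted p = 0.0226), and no list was shifted as a whole. Of these genes 10 passed over all 14329 probes, 17 after averaging the near-identical secondary duct arrays, and from 19 to 804 when any 1 of the 8 arrays was left out. Krt17, Krt19, Wnt6 and Wnt10a did not pass over all 14329 probes or after averaging. Quantile normalization and centring moved the higher share from 64.2% to 42.0% and 49.3%. The medians over all probes were 0.12 for bud and 0.15 for main duct against secondary duct. Main and secondary duct were on separate slides, and only the main duct columns carry the wash mark.

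At E15 the bud was marked by secretory genes and the main duct by keratins, WNT genes and a cell cycle inhibitor, with 5 bud and 7 main duct arrays. Of 10 acinar and secretory genes 9 were higher in bud and none was lower (10 higher adjusted over the list alone), with a median of 4.91. Dcpp2, a demilune cell secretory protein, was higher by 6.53 ± 1.76 (adjusted p = 0.0071) and Cldn10, an ion-selective claudin, by 6.25 ± 2.04 (adjusted p = 0.0177). Chosen after their values were seen, Aqp5 was higher by 4.81 ± 0.76 (adjusted p = 0.000263), lactoperoxidase (Lpo) by 4.31 ± 0.48 (adjusted p = 1.73e-05) and the acinar transcription factor Bhlha15 by 3.85 ± 0.54 (adjusted p = 0.000115). Of 18 ductal genes 15 were lower in bud and 1 was higher, with a median of -1.78. Krt7 was lower, at -4.08 ± 0.20 (adjusted p = 8.95e-10) and Krt5 at -4.61 ± 0.54 (adjusted p = 2.52e-05). The ductal shift held under both correlations (adjusted p = 1.3e-08, and 0.0397 with an estimated correlation), and the acinar shift had adjusted p = 0.00143, and adjusted p = 0.31 with an estimated correlation. Of 22 cell cycle genes 18 were higher and 1 was lower (19 and 1 adjusted over the list alone), with a median of 0.87 (adjusted p = 0.0215, and adjusted p = 0.392 with an estimated correlation). Ccnd1 was higher by 2.11 ± 0.54 (adjusted p = 0.00533) and Cdkn1a was lower, at -5.66 ± 0.85 (adjusted p = 0.000175).

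Of 7 WNT genes at E15, 5 were lower in bud than in main duct and 1 was higher, with a median of -2.89 (adjusted p = 0.0151, and adjusted p = 0.0947 with an estimated correlation and 0.16 with slide as a block). Wnt10a was lower, at -7.28 ± 1.23 (adjusted p = 0.000406), and so was the WNT target Axin2, at -4.70 ± 0.75 (adjusted p = 0.000285). The receptor Fzd10 was lower, at -5.34 ± 1.35 (adjusted p = 0.00498), which turned to 0.39 with slide as a block. Of 9 cleft and matrix genes 5 were lower, with a median of -0.84 (adjusted p = 0.0121, and adjusted p = 0.0947 with an estimated correlation and 0.0622 without the main duct arrays of slide 5). Timp3 was lower, at -3.92 ± 0.49 (adjusted p = 4.21e-05). Of 6 immediate early genes 5 were lower and 1 was higher, with a median of -1.44 (adjusted p = 0.0299, and adjusted p = 0.0947 with an estimated correlation). In camera this shift also no longer passed after centring (adjusted p = 0.0521), without the main duct arrays of slide 5 (0.0614) or with slide as a block. Jun was lower, at -2.79 ± 0.42 (adjusted p = 0.000182). Sox10 was higher by 3.76 ± 0.60 (adjusted p = 0.000269), in an FGF list with 6 higher and 1 lower of 10 (7 and 1 adjusted over the list alone). The stratified list was split, with 3 higher and 6 lower of 12. Pdgfra was lower in bud, at -3.60 ± 1.15 (adjusted p = 0.0156), and became 1.11 with slide as a block. Myod1, a myogenic factor, was higher by 1.70 ± 0.58 (adjusted p = 0.0208) and became -0.68 with the block. Cyp2f2 was lower, at -6.89 ± 0.28 (adjusted p = 1.22e-10), and the potassium channel Kcnn4 was higher by 5.67 ± 0.84 (adjusted p = 0.000157).

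In total 1718 genes were higher and 1056 lower in E15 bud than in main duct, 2774 of 4369, and 1848 passed over all 14329 probes. Among the probes of the tables over age 837 were higher and 487 lower. Only part of the E15 arrays shared slides, and with slide as a block, where bud and main duct are compared through the secondary duct, 84 genes passed, among them Krt7, Krt5, Cyp2f2, Ccnd1 and Dcpp2. Aqp5, Lpo, Bhlha15, Cldn10, Cdkn1a, Wnt10a, Axin2, Timp3, Jun, Sox10 and Kcnn4 kept their sign with the block and did not pass. With the block the bud side rests on bud array 5 alone, the only E15 bud array on a slide that also held duct arrays. Without the 4 main duct arrays of slide 5 the count was 1335. The authors' deposited folds were smaller than these differences for Dcpp2, at 3.06 in log2, Kcnn4, at 4.48, and Wnt10a, at -3.72. The median over all probes was 0.66, and the higher share moved from 61.9% to 45.0% after quantile normalization and to 38.0% after centring. The cell cycle shift no longer passed after centring (adjusted p = 0.0521), after quantile normalization (0.0581), with slide as a block (0.106) or without the main duct arrays of slide 5 (0.0622), with a range of 0.0198 to 0.392 over its alternatives.

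Against the E15 secondary duct (5 arrays each), the bud again had higher secretory and lower ductal genes. Of 10 acinar genes 9 were higher and none was lower, with a median of 4.48 (adjusted p = 0.000146, and adjusted p = 0.222 with an estimated correlation). Cldn10 was higher by 7.95 ± 2.20 (adjusted p = 0.0136). Of 18 ductal genes 14 were lower and none was higher, with a median of -1.68 (adjusted p = 4.07e-09, and 0.0464 with an estimated correlation). Krt7 was lower, at -3.90 ± 0.21 (adjusted p = 5.86e-09) and Tfcp2l1 at -3.67 ± 0.19 (adjusted p = 4.27e-09). Of 22 cell cycle genes 14 were higher and 1 was lower (15 and 1 adjusted over the list alone), with a median of 0.84 (adjusted p = 0.000495, and adjusted p = 0.222 with an estimated correlation). Of 7 WNT genes 4 were lower, with a median of -1.74 (adjusted p = 0.0102, and adjusted p = 0.154 with an estimated correlation and 0.141 with slide as a block). Cdkn1a was lower, at -4.50 ± 0.92 (adjusted p = 0.00278) and Wnt10a at -6.68 ± 1.33 (adjusted p = 0.00238). In total 949 genes were higher and 798 lower, 1747 in all, with 940 over all 14329 probes and 188 with slide as a block, among them Krt7, Tfcp2l1, Cdkn1a and Wnt10a and without Cldn10. With the block the bud side of this comparison, too, rests on bud array 5 alone. The median over all probes was 0.16, and the higher share moved from 54.3% to 40.7% after quantile normalization and to 42.8% after centring.

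E15 main duct (7 arrays) and secondary duct (5 arrays) differed by 358 genes higher and 890 lower, 1248 in all. The limma count was 0 without the 4 main duct arrays of slide 5, 0 with slide as a block and 2189 with only those 4. Of 5 mesenchyme genes 2 were higher in main duct (3 adjusted over the list alone), with a median of 2.43 (adjusted p = 0.0475, and adjusted p = 0.724 with an estimated correlation). These were Pdgfra at 3.58 ± 1.15 (adjusted p = 0.0387) and the collagen Col1a1 at 2.93 ± 0.99 (adjusted p = 0.0424). Of 18 ductal genes 3 were higher and 1 was lower, such as Tfcp2l1 at 3.64 ± 1.15 (adjusted p = 0.0383). Ido2 was lower, at -5.01 ± 1.60 (adjusted p = 0.0386). Over all 14329 probes 29 passed, without Pdgfra, Col1a1, Tfcp2l1 or Ido2. Leaving out any 1 of the 12 arrays gave between 34 and 1619, the lowest without secondary duct array 4, and averaging main duct arrays 1 and 2, which correlated at r = 0.978, gave 94. The higher share moved from 28.7% to 69.4% after quantile normalization and to 68.7% after centring, with a median over all probes of -0.24.

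From E12.5 to E15 Aqp5 and other secretory genes rose in the bud, with 3 arrays at E12.5 and 5 at E15. Aqp5 rose by 10.25 ± 0.64 (adjusted p = 9.46e-08), Lrrc26, a potassium channel subunit, by 9.11 ± 0.68 (adjusted p = 4.71e-07), and Bhlha15 by 7.29 ± 0.91 (adjusted p = 4e-05). Wfdc18, a secreted whey acidic protein family member, rose by 7.60 ± 0.59 (adjusted p = 5.52e-07). In the acinar list 5 of 8 genes rose and none fell, with a median of 2.40 (adjusted p = 0.00391, and adjusted p = 0.359 with an estimated correlation). Among them were Lpo at 4.28 ± 0.53 (adjusted p = 3.74e-05) and Elf5, an epithelial ETS factor, at 3.13 ± 0.34 (adjusted p = 1.34e-05). All 4 muscle genes rose, with a median of 3.91 (adjusted p = 0.0123, and adjusted p = 0.359 with an estimated correlation). The smooth muscle actin Acta2 rose by 4.88 ± 0.40 (adjusted p = 8.1e-07). In the FGF list 6 of 12 genes fell and 1 rose, with Etv4 at -2.17 ± 0.45 (adjusted p = 0.0017) and the feedback inhibitor Spry4 at -1.88 ± 0.39 (adjusted p = 0.00164). In the ductal list 8 of 15 rose and 2 fell, with Krt7 at 3.92 ± 0.61 (adjusted p = 0.00026) and Krt15 at -2.95 ± 0.69 (adjusted p = 0.00364). Of 13 stratified genes 7 rose and 1 fell, of 13 basement membrane genes 1 rose and 6 fell, and of 3 blood genes 2 rose. Alas2 rose by 6.04 ± 0.91 (adjusted p = 0.000201). The largest fall was that of Crym, a thyroid hormone binding protein, at -7.87 ± 1.24 (adjusted p = 0.000285). In total 1421 genes rose and 1249 fell of 6053, with 2274 over all 14329 probes. Among 1287 probes of the tables within age 205 rose and 214 fell. Over all genes 1416 rose and 1595 fell after quantile normalization and 1277 and 1380 after centring. No slide held both ages, so age and slide cannot be told apart.

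In the main duct (4 and 7 arrays) Cxcl17 rose from E12.5 to E15 by 10.47 ± 0.57 (adjusted p = 4.08e-09), Wfdc18 by 9.09 ± 0.38 (adjusted p = 2.21e-10) and Lrrc26 by 8.90 ± 0.61 (adjusted p = 6.09e-08). Pglyrp1, a peptidoglycan recognition protein, rose by 7.59 ± 0.69 (adjusted p = 1.33e-06). In the ductal list 12 of 17 genes rose and 1 fell (12 and 2 adjusted over the list alone), with a median of 1.38 (adjusted p = 0.000282, and adjusted p = 0.376 with an estimated correlation). Krt23 rose by 6.17 ± 0.35 (adjusted p = 6.87e-09), Krt7 by 4.95 ± 0.34 (adjusted p = 6.6e-08) and Tfcp2l1 by 8.32 ± 1.56 (adjusted p = 0.00078). Krt15 fell by 3.37 ± 0.41 (adjusted p = 2.21e-05). Of 9 mesenchyme genes 6 rose and none fell, with a median of 2.64 (adjusted p = 0.0473, and adjusted p = 0.914 with an estimated correlation). The shift also no longer passed without the main duct arrays of slide 5 (adjusted p = 0.451), after centring (0.112) or with the median over probes (0.0572). Among them were Col1a1 at 4.70 ± 0.98 (adjusted p = 0.00164) and the matrix proteoglycan Dcn at 4.10 ± 0.98 (adjusted p = 0.00368). Of 14 stratified genes 1 rose and 6 fell, without a shift of the list, and of 5 blood genes 1 rose and 3 fell, including the embryonic globin Hbb-y at -4.36 ± 1.20 (adjusted p = 0.0082). Aqp3 fell by 7.06 ± 1.25 (adjusted p = 0.000496). The LIM homeobox factor Isl1 fell by 6.06 ± 1.14 (adjusted p = 0.000805) and the death receptor Fas fell by 5.64 ± 0.68 (adjusted p = 2.21e-05). Of 5 endothelial genes 1 rose (0 adjusted over the list alone), and of 11 housekeeping genes 2 rose and 6 fell. In total 1246 genes rose and 1967 fell of 6011, with 2651 over all 14329 probes. Among 1287 probes of the tables within age 199 rose and 258 fell, 457 in all. No slide held both ages. The median over all probes was -0.50, and the higher share moved from 38.8% to 49.2% after quantile normalization and to 53.4% after centring.

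The bud to main duct difference itself changed from E12.5 to E15 for 150 of the 1140 genes measured at both ages in bud and main duct, 75 in each direction, over 19 arrays. It moved toward the bud for Elf5 by 2.73 ± 0.36 (adjusted p = 0.000136) and Isg20, an interferon-induced exonuclease, by 5.48 ± 0.55 (adjusted p = 1.53e-05). It did so for Rab3d, a secretory granule GTPase, by 3.94 ± 0.57 (adjusted p = 0.000262). It moved toward the main duct for Tnfrsf19 by -4.33 ± 0.46 (adjusted p = 2.11e-05), Aldh1a3 by -6.14 ± 0.85 (adjusted p = 0.000151) and the adenylate cyclase Adcy8 by -6.38 ± 1.17 (adjusted p = 0.00148). The same held for Tfcp2l1 by -3.11 ± 0.48 (adjusted p = 0.000375) and Krt23 by -2.40 ± 0.41 (adjusted p = 0.000899). Among lists, 2 of 3 acinar genes moved toward the bud and none the other way, with a median of 2.95. So did 3 of 8 stratified genes (5 adjusted over the list alone), with a median of 1.60. Each of these lists had adjusted p = 0.0168, and adjusted p = 0.158 with an estimated correlation. Ductal genes moved toward the main duct, 2 of 14 (3 adjusted over the list alone) with a median of -0.98 (adjusted p = 0.0168, and adjusted p = 0.273 with an estimated correlation). This shift was lost after quantile normalization (adjusted p = 0.651, the highest of a range from 0.00154). Over all 14329 probes 46 genes passed, and leaving out E12.5 bud array 2 or 3 gave 98 and 94. Bud and main duct shared slides at E12.5 but none at E15, so a slide difference at E15 cannot be told apart from this change. The higher share moved from 50.0% to 35.9% after centring, and the median over all probes was 0.22.

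**Figure D2:**
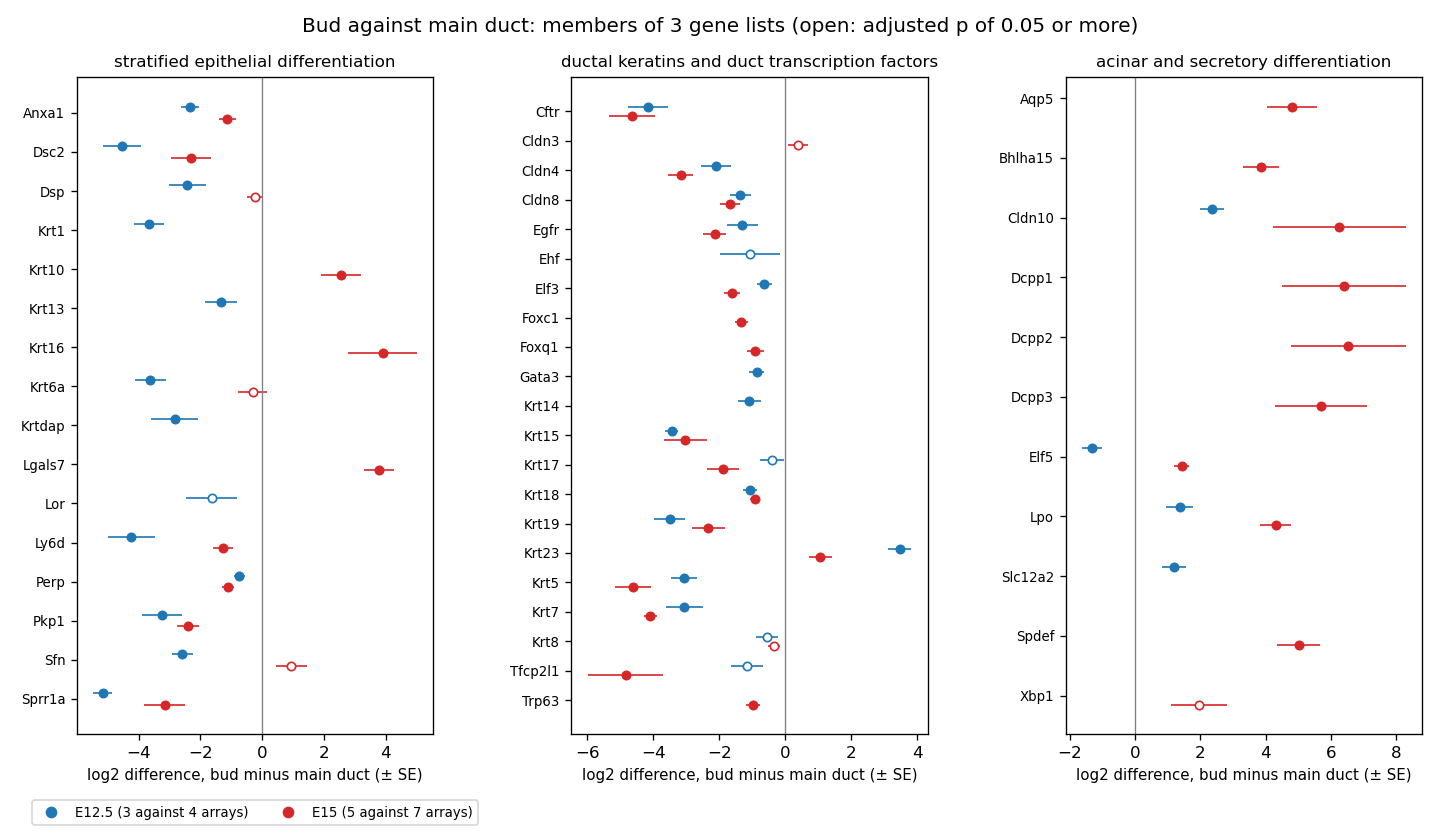
Log2 difference between bud and main duct (± SE) of each measured gene of the stratified, ductal and acinar lists at E12.5 and E15, with open points where the adjusted p was 0.05 or more. The list medians were -2.83 for stratified and -1.16 for ductal genes at E12.5, and -1.78 for ductal and 4.91 for acinar genes at E15.

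Most genes that separated bud from main duct at E12.5 and were measured again had the same sign at later ages. The later tables hold 414 to 714 of the 1648 genes, and list only probes that passed the authors' test at that age, so a gene whose difference was lost tends to be absent. Of those measured, 474 of 543 had the same sign in central bud at E13.5, 353 of 414 at E14 and 593 of 714 at E15. At E14, 101 genes were higher in bud at both ages where 54.1 would be shared by chance, and 128 were lower where 60.1 would be. At E15 these numbers were 239 against 165.6 and 194 against 86.8. A score over those of the E12.5 genes that had the same probe at the later age and lay outside the set of 114 probes (1635 at E12.5, 450 at E13.5, 334 at E14 and 586 at E15) was taken as the mean of each array's log2 values signed so that main duct genes count as positive. By group means it placed secondary ducts above buds and below main ducts. At E14 it averaged 0.39 in secondary duct, with an SD of 0.015 over 4 arrays. This was 0.34 below the main duct (exact permutation test, two-sided, n = 4 and 4, p = 0.0286, adjusted 0.0316). It was 1.05 above the bud (exact permutation test, n = 4 and 3, p = 0.0286, adjusted 0.0316). At E15 it was 0.12 below the main duct (exact permutation test, n = 5 and 7, p = 0.0316). It was 1.25 above the bud at that age (exact permutation test, n = 5 and 5, p = 0.00794, adjusted 0.0316). The probes scored at E14 and E15 had passed the authors' test on labels that separate these groups. This favours differences between them, so the permutation tests cannot exclude chance. The E14 p-values are the smallest that so few arrays allow. They also count secondary duct arrays 2 and 3, which correlated at r = 0.942, as separate arrays. At E13.5 the secondary duct averaged 0.10 with an SD of 0.26 over 3 arrays, the main duct 1.08 (SD 0.29) and the central bud -0.64 (SD 0.35).

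**Figure D3:**
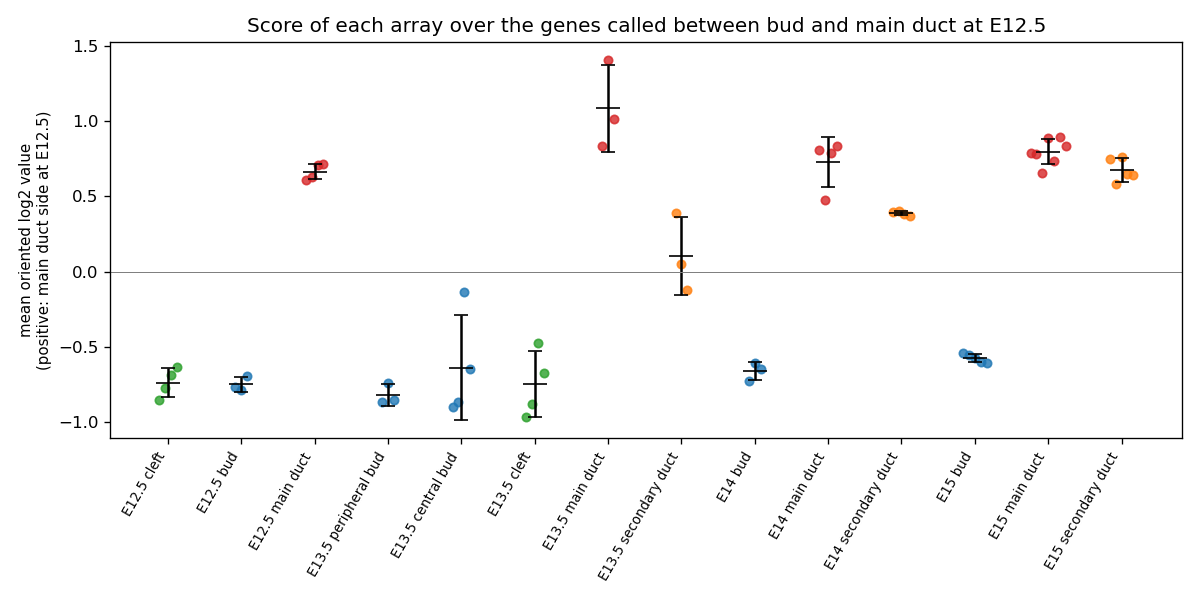
Score of each array over the 334 to 1635 genes used at each age (mean signed log2 value, main duct positive), by age and place, with the mean and SD of each group. Secondary duct arrays lie at 0.371 to 0.405 at E14 and 0.580 to 0.764 at E15, above every bud array of their age.

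The authors' deposited table of pathways was made from their own bud and main duct gene lists, with central bud alone at E13.5. It had 1 of 19 pathways higher in central bud and 7 of 21 lower at E13.5 with a Benjamini-adjusted p under 0.05. At E15 7 of 27 were higher and 11 of 33 lower. At E12.5 these numbers were 0 of 15 and 2 of 15, and at E14 they were 0 of 5 and 0 of 2.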

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

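The tests of the 3 weighed patterns and the stated outcome of each split count were written down only after their results had been seen. Genes and array measures were set apart when 1 array of a group of 4 to 7 lay far from the others by Dixon's criterion. This happened in 32 of 393 gene and group pairs and 3 of 45 array measures, where chance would give about 1 in 20.

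At E15, bud array 1 had the widest interquartile range of log2 values in its group at 1.45, and lay apart in Aqp5 at 6.73, Lpo at 6.472, Myod1 at 2.829 and Sfrp1 at -3.615. Secondary duct array 5 at E15 lay apart in the keratins Krt5 at 3.316, Krt15 at 1.983 and Krt17 at 3.035, in Jun at 1.239 and in Elf5 at -0.416. Main duct arrays 5 and 6 at E15 lay apart in Tnfrsf19 at 0.356 and Spry4 at -6.682, and bud array 4 in Wnt5b at -4.939. At E12.5, main duct array 4 lay apart in the stefins Stfa1 at 2.347 and Stfa3 at 2.771, and in Edar at -0.086, Etv4 at -1.697 and Lpo at -1.649. Main duct arrays 2 and 3 at E12.5 lay apart in Esrp1 at -0.042 and Pglyrp1 at -6.141, and cleft array 4 in Ccl20 at 1.558 and Krt15 at 0.254. At E14, secondary duct array 4 lay apart in Cdh1 at 2.037, Cftr at -2.022, Dsc2 at -2.635 and Spry4 at -6.641, and arrays 1 and 3 in Cldn10 at -1.375 and Krt19 at 0.358. Main duct array 1 at E14 had a mean correlation of 0.582 with its own group, and main duct array 2 a location score of 0.479. At E13.5, central bud array 3 lay apart in Krt15 at 2.155, Ccnd1 at 0.209 and Shisa2 at -0.277, and cleft arrays 3 and 2 in Dusp6 at 0.527 and Tfcp2l1 at -4.899. The bud to main duct difference changed between E12.5 and E15 for 150 genes, by the interaction term given in the report.

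The first weighed pattern was the set of 114 probes at least 32-fold apart between main duct and both bud groups at E13.5, such as Tcaf1 and Insl5. The highest E12.5 main duct array lay at 0.285 on the axis from bud (0) to main duct (1), over 86 of the probes. Only 20 of the probes were measured in E12.5 cleft, so most of the 86 came from the tables over age. Those list probes that had passed the authors' test between ages, which favours a low position at E12.5. These values therefore cannot decide on a difference between duct and bud that holds at every age. A difference between slides was in line with the secondary duct array of slide 2, which exceeded the higher of the other two, from slide 6, by 0.755. The lowest E14 bud array lay at 0.476 over 78 of the probes, and the highest bud array of other ages at 0.270 over 82. A difference at E13.5 alone cannot be told apart from slide, because no E13.5 bud array shared a slide with a main duct array.

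The second weighed pattern was the 1248 genes between main and secondary duct at E15, such as Pdgfra and Ido2. Without the 4 main duct arrays of slide 5 the count was 0, and with only those 4 for the main duct it was 2189, which is in line with a difference between slides. Leaving out secondary duct array 4 alone gave 34, so the loss of arrays is not excluded as part of the fall. Position in the gland as the whole cause was argued against, since the 3 main duct arrays of slides 9 and 10 correlated by 0.309 more with secondary duct arrays (r = 0.541) than with main duct arrays of slide 5 (r = 0.233). A smaller difference between the ducts at E15 stays open.

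The third weighed pattern was the correlation of 0.901 between central bud array 3 and secondary duct array 3 at E13.5. Duct material in central bud array 3, by a wrong label or a mixed sample, was in line with its location score of -0.139, above -0.648, the highest of the other central bud arrays, and with its Krt15 value given above. Bud material in secondary duct array 3 was in line with its mean correlation with the 6 other bud arrays, higher by 0.498 (r = 0.391) than with the 2 other arrays of its group (r = -0.107). Which of the 2 arrays was out of place stays open, since central bud array 3 correlated at a mean r of 0.589 with its own group and the 2 scores were close, at -0.139 and -0.125. No biological explanation was tested, since the labels give none for a single array.

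Splits of the same arrays were counted for each comparison, and every number of splits given below includes the real one. For peripheral against central bud (highest other 0) and peripheral bud against cleft (highest other 27) the real count of 0 fixes that all 35 of the 35 splits give as many, so the splits decide nothing. For central bud against cleft, 2 of the 35 splits gave as many as the real 6, with a highest other of 42, and for central bud against secondary duct 2 of the 35 gave as many as 15, with a highest other of 38. The 42 came from central bud array 1 with cleft arrays 1, 2 and 4 against the rest, and the 38 from central bud array 3 with the 3 secondary duct arrays, so these higher counts point to a structure of the samples other than the labels. Chance was not excluded for these comparisons of central bud. On probes of the tables over age, 2 of the 35 splits gave as many as the real 301 genes for E14 bud against main duct, with 411 in the split that joined main duct array 2 to the buds, so chance was not excluded there either.

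For the remaining splits, every probe had already passed the authors' test on labels that separate these arrays, which favours the real split, so the counts below decide nothing. At E12.5, 1 of the 35 splits gave as many for bud against main duct (1648, highest other 173), 1 of the 35 for cleft against bud (14, highest other 6) and 1 of the 35 for cleft against main duct (2490, highest other 1). For central bud against main duct it was 1 of the 35 (2046, highest other 866), and that highest split put central bud array 3 with the main ducts. At E14 it was 1 of the 35 for bud against main duct (936, highest other 655), bud against secondary duct (423, highest other 1) and main against secondary duct (595, highest other 3). At E15 it was 1 of the 100 for bud against main duct (2774, highest other 929) and bud against secondary duct (1747, highest other 11). For main against secondary duct it was 3 of the 100 (1248, highest other 1824), and that highest split put main duct arrays 1 to 5, with all 4 of slide 5, against the rest. That split kept slide 5 together and parted slide 9, and with slide as a block 0 genes passed in limma between the E15 ducts. Over age it was 1 of the 56 for bud (2670, highest other 44), 1 of the 100 for main duct (3213, highest other 281) and 1 of the 100 for the interaction (150, highest other 25).

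On probes of the other set of tables, which were also tested on labels that part some of these arrays, 1 of the 35 splits gave as many at E12.5 (42, highest other 3), 1 of the 35 for central bud (1473, highest other 981) and 1 of the 100 at E15 (1324, highest other 936). For bud over age it was 1 of the 56 (419, highest other 34) and for main duct over age 1 of the 100 (457, highest other 224). With 3 arrays against 3 there are only 10 splits, too few for a share under 0.05. For peripheral bud against main duct 1 of the 10 gave as many (2302, highest other 0, and 1522, highest other 1, on the other probes), for peripheral bud against secondary duct 1 of the 10 (633, highest other 57) and for main against secondary duct at E13.5 1 of the 10 (7, highest other 3).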

How the results depend on the processing

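The alternatives named below as added were chosen after the files had been opened, and the rest were planned. The main limits are that the tables hold only probes the authors' own test had passed, that slide and place are confounded at E13.5 and E14 and only partly shared at E15, that the labels do not tie captured regions to animals, and that groups hold 3 to 7 arrays. No paired analysis was possible because the array columns carry no replicate numbers of the labels. The cause of a moved count was not tested unless the text says so. Counts are genes that passed in limma, and a count is given where it moved more than 1.5 times.

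Adjusting over all 14329 distinct probes (added) can only lower or keep a count, and moved 16 of 20. At E12.5 it left 658 genes for bud against main duct, 0 for cleft against bud and 1508 for cleft against main duct. At E13.5 it left 1155 for central bud and 1466 for peripheral bud against main duct, 0 for central bud against cleft, 2 for central bud and 0 for peripheral bud against secondary duct, and 0 between the ducts. At E14 it left 94 for bud against main duct, 23 for bud against secondary duct and 10 between the ducts, at E15 1848, 940 and 29 in the same order, and 46 for the interaction. Of named genes 1247 calls were unchanged and 299 were lost.

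Slide as a fixed block (added) left 84 genes for E15 bud against main duct, 188 for bud against secondary duct and 0 between the ducts, and moved no E12.5 count. It reversed Fzd10 to 0.393 and Pdgfra to 1.108 for E15 bud against main duct, and Myod1, E15 bud against main duct, to -0.677. At E15 the bud side of these fits rests on bud array 5 alone, so the reversals may reflect that array. Slide as a random block (added) left 1217 genes for central bud against main duct and 0 each for central bud against cleft, central and peripheral bud against secondary duct, and the E13.5 ducts. Without the 4 main duct arrays of slide 5 (added) 1335 genes were left for E15 bud against main duct and 0 between the E15 ducts, and with only those arrays 2189 passed between the ducts and 433 for the interaction. Averaging near-identical arrays (added) left 98 genes for E14 bud against secondary duct, 17 between the E14 ducts and 94 between the E15 ducts. Without central bud array 3 and secondary duct array 3 (added) there were 0 for central bud against cleft, 1002 and 1304 for central and peripheral bud against secondary duct, and 1 between the E13.5 ducts.

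Quantile normalization gave 48 genes for E12.5 cleft against bud, 16 for central bud against cleft, 42 for central bud against secondary duct, 1 between the E13.5 ducts and 366 between the E15 ducts. Centring each group gave 32 for central bud against secondary duct and 20 between the E13.5 ducts. Leaving out the dimmest 25% of probes gave 6 for E12.5 cleft against bud, 29 and 395 for central and peripheral bud against secondary duct, and 2 between the E13.5 ducts. Fitting only the groups compared gave 6 for E12.5 cleft against bud, 13 for central bud against cleft, 0 for central and 0 for peripheral bud against secondary duct, 0 between the E13.5 ducts, 407 for E14 bud against main duct, 151 between the E14 ducts and 39 between the E15 ducts. Counting probes gave 1 for peripheral bud against cleft. Taking the median over a gene's probes moved no count and reversed 1 named gene, Col4a1 between the E15 ducts, to 0.014.

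Keeping only probes with the authors' p of at most 0.01, which shortens the tables, gave 128 for E12.5 cleft against bud, 1276 for cleft against main duct, 1159 and 1250 for central and peripheral bud against main duct, 65 for central bud against cleft, 46 for central bud against secondary duct, 95 between the E13.5 ducts, 459 for E14 bud against main duct, 296 between the E14 ducts, 766 between the E15 ducts and 79 for the interaction. Adjusting the authors' p within a table could drop no probe, since every p there is already at most 0.05. Its unchanged counts therefore decide nothing. The tables over age hold other probes, and arrays of other ages. They gave 42 at E12.5, 1522 for peripheral bud, 301 at E14 and 1324 at E15 for bud against main duct. The tables within age gave 419 for bud and 457 for main duct over age. For the interaction, all probes with values at both ages gave 333, and counting absence from a table as no change gave 2968.

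Leaving out 1 array at a time gave these lowest and highest counts. At E12.5 they were 864 and 1416 for bud against main duct, 0 and 31 for cleft against bud, and 2105 and 2306 for cleft against main duct. At E13.5 they were 1323 and 1960 for central bud against main duct, 1751 and 2004 for peripheral bud against main duct, 0 and 0 between the buds, 0 and 143 for central bud against cleft, 0 and 1 for peripheral bud against cleft, 0 and 1025 for central bud against secondary duct, 0 and 1335 for peripheral bud against secondary duct, and 0 and 411 between the ducts. At E14 they were 429 and 997, 72 and 230, and 19 and 804 for bud against main duct, bud against secondary duct and the ducts. At E15 they were 2272 and 2835, 1233 and 1703, and 34 and 1619 in the same order. Over age they were 1889 and 2565 for bud, 2437 and 3175 for main duct, and 94 and 193 for the interaction. No named gene was reversed by leaving out an array.

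Of the 57 list shifts that passed, 4 did so with an estimated correlation. These were the stratified list for bud and for cleft against main duct at E12.5, and the ductal list for bud against main duct and against secondary duct at E15. Quantile normalization ended 6, centring 4, slide as a fixed block 5 and leaving out the main duct arrays of slide 5 also 5, with some lists ended by several of these. Among those ended by the block were the WNT list of E15 bud against main duct (adjusted p = 0.16) and against secondary duct (adjusted p = 0.141).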

Other observations

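The score tests of secondary ducts and the count of genes that kept their direction were chosen after the results had been seen. Krt23 went against the ductal list at every age, higher in bud than in main duct by 3.47 ± 0.36 (adjusted p = 0.000209) at E12.5 and by 2.76 ± 0.55 (adjusted p = 0.00256) in central bud at E13.5. Its lead in bud shrank by 2.40 ± 0.41 (adjusted p = 0.000899) from E12.5 to E15, while it rose in main duct by 6.17 ± 0.35 (adjusted p = 6.87e-09). Krt15 fell with age, in bud by 2.95 ± 0.69 (adjusted p = 0.00364) and in main duct by 3.37 ± 0.41 (adjusted p = 2.21e-05).

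Tnfrsf19 changed sides, higher in bud by 3.02 ± 0.58 (adjusted p = 0.0042) at E12.5 and lower, at -1.77 ± 0.31 (adjusted p = 0.000596), at E15, and the latter call held with slide as a block. Krt7, Cyp2f2 and Tfcp2l1 were lower in bud than in either duct at E14, where bud and ducts were on separate slides. Cyp2f2 and Krt7 were lower in E15 bud than in either duct with slide as a block as well. With that block, for Tnfrsf19 too, the bud side rests on bud array 5, the only E15 bud array sharing a slide with ducts.

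Genes that separated bud from main duct at E12.5 had the same sign later in at least 83.1% of those measured at each age. Only 414 to 714 of the 1648 were measured there, since the later tables list only probes that passed the authors' test at that age, so this does not show that the difference was kept. The secondary duct score at E14 lay 0.339 below that of the main duct (4 arrays each, exact permutation p = 0.0286), with every secondary duct array between every bud and every main duct array, which may mean that secondary ducts had moved less far from the bud than the main duct at that age. Slide was not shared at E14, and only the main duct columns carry a wash mark. The probes had also passed the authors' test on these labels, so the permutation test cannot exclude chance. The reading needs a test on slides that hold both ducts. At E15 the difference was 0.121 (exact permutation p = 0.0316) and the arrays of both ducts overlapped.

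The fall of 2 FGF response genes in bud over age, Etv4 at -2.17 ± 0.45 (adjusted p = 0.0017) and Spry4 at -1.88 ± 0.39 (adjusted p = 0.00164), came with the rise of Aqp5 and Bhlha15. A lower FGF response as acinar genes come on could be tested by staining for both in the same buds from E13.5 to E15. The tables of single ages share only 1287 probes between E12.5 and E15, where 419 genes passed for bud over age.

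The lower immediate early genes in bud than in main duct at E12.5, E14 and E15, such as Jun, could reflect handling of the tissue, which was not tested. As lists none of them passed in camera with an estimated correlation (adjusted p = 0.229, 0.221 and 0.0947 in that order). At E12.5 bud and main duct shared slides. With slide as a block at E15 the list no longer passed, at adjusted p = 0.213, the highest of its alternatives, and 84 genes passed in all. Mesenchyme genes such as Col1a1 rose in main duct over age by 4.70 ± 0.98 (adjusted p = 0.00164), which could come from tissue around the duct taken along with it. Their shift over age no longer passed without the main duct arrays of slide 5 (adjusted p = 0.451). Between the E15 ducts they passed only with the main duct arrays of slide 5, with 0 genes of any kind past in limma without them.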
